A study of Arabidopsis thaliana with 12 samples.

How the data were processed

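Total RNA from leaves of Col-0 and ago1-27 plants was labelled with biotin by a 3' in vitro transcription kit and hybridised to ATH1 arrays, 12 in all, per the labels. The deposited table holds 1 signal intensity per probe set and array, 22810 probe sets on a linear scale, made with MAS5 per the submitters' processing notes, which give no version. The values bear this out in part: every array has a 2% trimmed mean of 500, so the arrays were scaled to a common target. No detection calls are in the deposited table, and raw probe values were not analysed here. All 12 columns were mapped to a sample, and groups were taken from the labels: wild type and ago1-27, each in the dark and submerged, with 3 biological replicates per group. For arrays, the number of arrays limits the precision.

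Probe sets were named with the annotation table supplied for this work, which assigns 1 gene to 13513 probe sets, of which 13436 matched a gene of the RefSeq annotation and 77 did not; 503 name several genes and 8730 name none. Among the unnamed are the probe sets of AGO1 and of many well-known low-oxygen genes such as ADH1, PDC1, SUS1, HB1, HRE1, PCO1 and LBD41, so their values are not given. No coordinates are given, since the sources used here pair none with the probe sets. The 64 control probe sets were left out of the tests. A probe set was kept when its signal exceeded the array's 40th percentile on at least 3 of the 12 arrays, which left 14812.

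Signals were taken as log2 and fitted with limma 3.58.1 in R 4.3.3 as 4 group means, with moderated variances and an intensity trend (8 residual and 4.61 prior degrees of freedom). The 5 contrasts were submergence in each genotype, genotype in each treatment, and their interaction. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and a second count took changes of at least 2-fold. Errors of log2 changes are standard errors of the fit, and errors of signals are standard deviations over replicates. The 40th percentile of each array served as its low-signal limit: where all arrays of a group lay under it, the fold is given as a bound against that limit, and no fold is given where both groups lay under it. Genes to be named were fixed by a rule before the data were examined, as were the lists, the contrasts and the alternatives, except where the text says otherwise. The rule took, for each contrast, up to 12 genes with the largest rise and 12 with the largest fall among calls on probe sets that name 1 gene and have every array of a group above every array of the other, which 10% of genes would meet by chance at 3 against 3 arrays; no such demand was made for the interaction. It added AGO1, a fixed set of low-oxygen and small RNA genes where the annotation names them, and members of the lists. COX5b-1 is named AT3G15640 in the annotation, and CHI there is AT2G43570.

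Gene lists were written down from general knowledge: low oxygen, glycolysis and fermentation, starvation, photosynthesis, ribosome, microRNA targets, silencing, salicylic acid defence, jasmonate, ethylene, heat and oxidative stress, flavonoids, clock, cell wall growth, abscisic acid, cell division, and markers of flower, root and guard cells. They hold 467 genes, of which 88 are named on the array. Each gene was represented by its probe set with the highest mean signal. The 10 lists with at least 3 measured genes were tested in the 5 contrasts (50 tests) with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes; fry tests whether its genes move on balance in a direction, or in either direction for its mixed p, and compares with no other genes. The low-oxygen list was also set against 10000 random lists matched in expression. RNA quality ratios were tested with exact permutation tests over 924 splits. Shared calls were tested with Fisher's exact test, two-sided. The size of the submergence response was tested with fry on signed probe sets.

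Whether replicate numbers pair the arrays was checked: 8 of 18 pairs with the same number had a residual correlation above 0.1, over a range of -0.28 to 0.35, so the arrays were not treated as paired. The pipeline was tested on simulated data with the same design. It recovered 56%, 63%, 54%, 57% and 23% of 100 planted 2-fold changes in submergence in wild type, in ago1-27, genotype in the dark, under submergence and the interaction, and 92%, 97%, 83%, 91% and 71% of 4-fold changes, with 3 to 10 false calls among 14812. Of 300 simulated tests of unmoved lists with camera, 5.33% had a p under 0.05. The simulated genes were drawn independently of each other. This share therefore does not test the preset correlation on the real lists, where the estimated correlation was as high as 0.85 (ribosome).

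The alternatives were no filter, a stricter filter (60th percentile), quantile normalization, median centring, a floor at the 25th percentile, a pseudocount, no variance trend, a robust trend, array weights, only the 6 arrays of a contrast, the replicate number as a block, the mean over all probe sets of a gene, estimated correlation, fry, and leaving out each array in turn. An exclusion of 2 arrays that lay apart from their groups, and a test of gene families, were chosen after seeing the data. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.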

Results

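RNA from leaves of Arabidopsis thaliana plants 4 weeks old was hybridised to 12 Affymetrix ATH1 arrays, which fall into 4 groups of 3 biological replicates. The plants were Col-0 wild type or ago1-27, a hypomorphic mutant of ARGONAUTE1, the protein that binds microRNAs and is guided by them to their target transcripts. They were kept in the dark for 12 h, or submerged for 12 h in the dark with water 10 cm above the leaves, and RNA of 4 plants was pooled for each replicate. On every array the 2% trimmed mean of the deposited signals was 500, and the median signal ranged from 134 to 207. The number of arrays limits the precision of every value. Groups are named as the labels name them, and the labels could not be checked on AGO1 itself, since the annotation used here names no probe set for it.

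The first principal component held 68.2% of the variance and parted the arrays labelled ago1-27 from those labelled wild type, and the second held 11.1%. The GAPDH ratio of RNA quality moved with the labelled genotype as well. The 3' to 5' ratio of the GAPDH control probe sets was 1.95 ± 0.24 on the arrays labelled ago1-27 and 1.35 ± 0.11 on those labelled wild type (SD, n = 6 each, two-sided exact permutation test over 924 splits, p = 0.0022, Benjamini-Hochberg p = 0.013 over 6 tests). The actin ratio was 9.72 ± 2 against 7.13 ± 1 (exact p = 0.022, adjusted p = 0.066), and the ubiquitin ratio 2.99 ± 0.39 against 2.76 ± 0.17 (exact p = 0.23, adjusted p = 0.34). Pooled over both genotypes, the labelled treatments gave an exact p of 0.85 for GAPDH, 0.49 for actin and 0.035 for ubiquitin (adjusted p = 0.07 for ubiquitin). For actin the pooled values hide opposite shifts: the ratio was 8.02 ± 0.86 in ago1-27 in the dark and 11.4 ± 0.989 in submerged ago1-27, but 7.95 ± 0.477 in wild type in the dark and 6.3 ± 0.63 in submerged wild type (SD, n = 3 each). Within each genotype the arrays of the treatments did not overlap, which chance gives in 10% of splits, and the genotypes differed in actin under submergence but hardly in the dark. The signal of the 25S ribosomal RNA control was 8320 ± 1700 in submerged ago1-27, 15600 ± 840 in ago1-27 in the dark, 17400 ± 1260 in submerged wild type and 20000 ± 1520 in wild type in the dark (SD, n = 3 each). WT_dark replicate 1 and ago1-27_submerged replicate 3 lay apart from the other arrays of their groups. The control probe set U12639 was at 27800 ± 2000 on the arrays labelled dark and at 18.1 ± 15.9 on those labelled submerged (SD, n = 6 each).

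**Figure D1:**
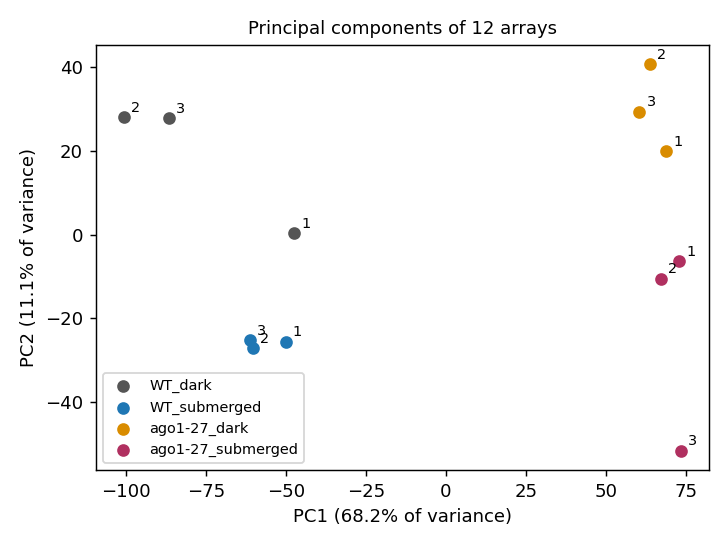
Scores of the 12 arrays on the first principal component (68.2% of the variance, horizontal axis) and the second (11.1%, vertical axis), from log2 signals, with each array numbered by its replicate. The arrays part by labelled genotype along the first component.

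In wild type, the comparison asks which leaf transcripts change when plants in the dark are also submerged. XTH33, an enzyme that remodels cell wall xyloglucan, rose from 112 ± 4.42 to 468 ± 109 (signal, SD, n = 3 each; log2 change 2.04 ± 0.25, SE; adjusted p = 0.001), and the expansin EXPA8 rose from 956 ± 260 to 2060 ± 565 (1.11 ± 0.26, adjusted p = 0.022). The lipid transfer protein gene AT4G12500 rose 8.48-fold, AT1G12080 6.93-fold, and AT3G55920 at least 3.21-fold from a level under the low-signal limit. AT3G07350 fell 5.5-fold, from 2550 ± 762 to 463 ± 137, AT3G28540 fell 8.42-fold, and AT3G48650 fell from 4220 ± 2570 to 56.3 ± 89.1. The copper chaperone gene CCS and the MADS-box gene AGL16, both microRNA targets, fell by 1.29 and 1.05 on the log2 scale. 2 genes known to be induced by low oxygen had similar signals in both wild-type groups. The signal of pyruvate decarboxylase PDC2 was 2840 ± 493 in the dark and 2710 ± 545 under submergence, and that of the calmodulin-like gene CML38 4410 ± 500 and 4820 ± 311. The actin 3' to 5' ratio fell in the same comparison, from 7.95 to 6.3.

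Of 14812 probe sets tested with limma, 1048 were called at an adjusted p under 0.05, 697 higher and 351 lower under submergence. Of these, 304 and 158 changed at least 2-fold, and 3336 probe sets had an unadjusted p under 0.05. The excess of rises depends on scaling. As deposited, 66.5% of the calls were higher, and after each array was centred on its median 52.1% were (514 higher, 473 lower). The median of all probe sets was 0.07. Of the 24 genes of the low-oxygen list, 1 rose (AT5G42200, log2 change 1.1 ± 0.24, adjusted p = 0.019), 0 fell and 23 were not called. The counts were the same adjusted over the list alone. The list's median log2 change was 0.14 (camera adjusted p = 0.96). Of 8 photosynthesis genes 3 rose, the antenna gene LHCB4.2 by 1.09 ± 0.22, PSAN of photosystem I by 0.72 ± 0.16 and PSBY of photosystem II by 0.55 ± 0.15 on the log2 scale. The other 5 were not called, and 4 rose adjusted over the list alone. Their median was 0.37 (camera adjusted p = 0.034, adjusted p = 0.88 with an estimated correlation, fry adjusted p = 0.11), and 0.28 after median centring (adjusted p = 0.07). Of 3 cell wall genes 2 rose, in the same number adjusted over the list alone, with a median of 1.11 (camera adjusted p = 0.035, adjusted p = 0.35 with an estimated correlation, fry adjusted p = 0.0061). Among 9 microRNA targets SNZ rose and CCS and AGL16 fell, the same adjusted over the list alone, with a median of -0.01 (camera adjusted p = 0.37). The signal of SNZ lay under the low-signal limit in both groups, so no fold is given, and with a floor on low signals it was not called (adjusted p = 0.31). No member was called, over all probe sets or adjusted over the list alone, in the lists of glycolysis and fermentation (5 genes, median 0.05, camera adjusted p = 0.99 with a test direction of down), starvation (5, -0.14, 0.41), ribosome (6, 0.14, 0.74), silencing (4, -0.02, 0.86), heat and oxidative stress (4, -0.53, 0.38) and cell division (3, 0.44, 0.99).

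The count fell to 320 without WT_submerged replicate 1, 496 without WT_submerged replicate 2, 450 without WT_dark replicate 2 and 455 without WT_dark replicate 3, and rose to 2506 without WT_dark replicate 1. It was 431 from the 6 arrays alone, 4419 with array weights and 3866 without the 2 arrays that lay apart, an exclusion chosen after seeing the data. The photosynthesis list was not called without WT_submerged replicate 1 (adjusted p = 0.096) or WT_dark replicate 2 (0.1), nor the cell wall list without WT_dark replicate 1 (0.11) or 2 (0.1) or with a floor on low signals (0.063). Single genes lost their call without an array too, here with the highest adjusted p. These were PSAN (0.088) and LHCB4.2 (0.071) without WT_submerged 1, WT_dark 2 or WT_dark 3, and EXPA8 (0.11) without these or WT_submerged 3. AT5G42200 (0.075) lost it without WT_submerged 1 or 2 or WT_dark 2 or 3, CCS (0.069) without WT_dark 2 or 3, and PSBY (0.19) without any array but WT_dark 1 and ago1-27_submerged 1 and 3.

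In ago1-27, the same comparison asks which transcripts change with submergence in the mutant. XTH33 rose from 141 ± 45.4 to 553 ± 82.6 (SD, n = 3 each; log2 change 2.02 ± 0.25, SE; adjusted p = 0.0011). AT1G73600, a phosphoethanolamine methyltransferase gene, rose 7.52-fold from 180 ± 18.7 to 1350 ± 175, and AT3G22240 rose from 2350 ± 663 to 11800 ± 4390. The jacalin-like lectin gene JAL22 rose at least 1.94-fold, and AT3G55920 at least 3.3-fold. The calmodulin-like gene CML41 fell from 891 ± 166 to 152 ± 42.5 (log2 change -2.58 ± 0.27, adjusted p = 0.00047), AT1G72060 fell from 2300 ± 480 to 413 ± 214, and AT1G76960 fell at least 5.08-fold. CCS and AGL16 fell by 1.49 and 1.69 on the log2 scale, with the same limit of the labels as in wild type. The low-oxygen genes lay at different levels in ago1-27. The signal of PDC2 was 114 ± 22.8 in the dark and 152 ± 74.8 under submergence, and CML38 lay under the low-signal limit in both, while AT4G27450 was at 7140 and 4080 and AT3G10020 at 1570 and 700, near its wild-type levels of 1550 and 666. RNA quality signs moved with submergence in ago1-27: actin as given above, the ubiquitin ratio from 2.72 ± 0.197 to 3.27 ± 0.328, and the 25S control from 15600 ± 840 to 8320 ± 1700.

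In all, 1241 probe sets were called, 621 higher and 620 lower, of which 207 and 198 changed at least 2-fold, and 3701 had an unadjusted p under 0.05. After median centring 41.5% of the calls were higher (534 higher, 753 lower), against 50% as deposited. Of the 24 low-oxygen genes 0 rose, 2 fell (AT4G27450 by 0.81 and AT1G33055 by 0.92 on the log2 scale) and 22 were not called, with the same counts adjusted over the list alone. Their median was 0.18, or 0.12 with members under the low-signal limit at their bound, while the test's direction was down (camera adjusted p = 0.84). Of 3 cell wall genes XTH33 rose, 2 adjusted over the list alone, with a median of 2.02, or 0.93 with bounds (camera adjusted p = 0.034, adjusted p = 0.35 with an estimated correlation, fry adjusted p = 0.0037). Among 9 microRNA targets SNZ rose, at least 1.71-fold, and CCS and AGL16 fell, while 2 rose and 2 fell adjusted over the list alone. The median was 0.06 with a test direction of down (camera adjusted p = 0.8). Of 5 starvation genes AKINBETA1, a subunit of the energy-sensing kinase SnRK1, fell by 1 ± 0.21 on the log2 scale, as adjusted over the list alone, with a list median of -0.46 (camera adjusted p = 0.051). Of 4 silencing genes TGH fell (log2 change -0.74 ± 0.21), 2 adjusted over the list alone, with a median of -0.26 (0.38). No member was called in the lists of glycolysis and fermentation (median 0.14, camera adjusted p = 0.74), photosynthesis (0.07, 0.96), ribosome (0.37, 0.18; 2 rose adjusted over the list alone), heat and oxidative stress (-0.58, or 0.17 with bounds, 0.42; 1 fell adjusted over the list alone) and cell division (0.7, 0.41).

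The count fell to 352 without ago1-27_dark replicate 2, 365 without ago1-27_dark replicate 3, 682 without ago1-27_submerged replicate 2 and 733 without ago1-27_submerged replicate 3, and rose to 1865 without WT_dark replicate 1 and 2701 with array weights. It was 1556 without the 2 arrays that lay apart. Without ago1-27_submerged replicate 3 the low-oxygen list had a median of -0.31 and was called lower (adjusted p = 0.0084), and without WT_dark replicate 1 the cell wall list was not called (0.05). Single genes lost their call too, here with the highest adjusted p. These were AKINBETA1 (0.068) without ago1-27_dark 2 or 3, AT1G33055 (0.11) and SNZ (0.095) without any of the 3 ago1-27_dark arrays, and TGH (0.16) without any array but WT_dark 1 and 2.

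**Figure D2:**
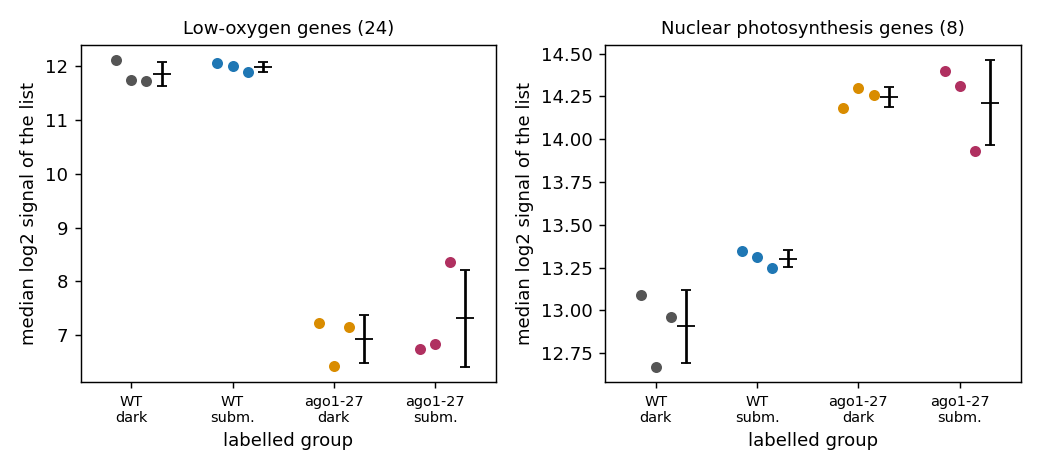
Median log2 signal of the 24 low-oxygen genes and of the 8 photosynthesis genes (vertical axis) on each array, by labelled group; points are arrays, and the bar with its error is the group's mean ± SD (n = 3). The low-oxygen medians lie from 11.72 to 12.12 on the 6 arrays labelled wild type and from 6.42 to 8.36 on the 6 labelled ago1-27.

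The submergence effects of both genotypes were compared across probe sets. AT3G55920, XTH33, CCS and AGL16 were called in the same direction in both. Of the probe sets called higher, 160 were shared (697 in wild type, 621 in ago1-27, 29.2 expected for independent lists, Fisher's exact p = 1.9e-76), and of those called lower, 129 were shared (14.7 expected, Fisher's exact p = 6.8e-89), while 9 were called in opposite directions. Across all 14812 probe sets the log2 changes correlated with a Pearson r of 0.44 and a Spearman rho of 0.36. Genes are not independent replicates, so neither these correlations nor the Fisher p values measure agreement over replicate plants. The contrasts share no arrays but share their variance estimate. The number shared, 289, was 546 without WT_dark replicate 1, 606 without the 2 arrays that lay apart and 1025 with array weights, and 160 when each contrast was fitted from its 6 arrays alone. It was 118 without ago1-27_dark replicate 2, 119 without ago1-27_dark replicate 3, 137 without WT_submerged replicate 1, and at most 192 without WT_submerged replicate 2 (174), WT_dark replicate 2 or 3, or ago1-27_submerged replicate 2 (186).

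In the dark, the comparison of ago1-27 with wild type asks what the mutation changes in leaves that were not submerged. Of 24 genes known to be induced by low oxygen, 23 were lower in the arrays labelled ago1-27. CML38 was at least 49-fold lower (4410 ± 500 in wild type, 37.5 ± 3.92 in ago1-27; SD, n = 3 each; adjusted p = 9.9e-10), AT5G66985 at least 97.4-fold, AT5G10040 at least 113-fold and AT3G29970 at least 124-fold lower. PDC2, the first enzyme of ethanol fermentation, was lower by a log2 change of -4.65 ± 0.29 (SE), the transcription factor gene AT3G10040 (HRA1) fell from 3710 ± 926 to 94.5 ± 28.8, and the lactate dehydrogenase gene AT4G17260 (LDH1) from 2230 ± 1030 to 250 ± 86.4. Photosynthesis genes were higher, LHCB4.2 by 2.51 ± 0.22 and PSAN by 2.01 ± 0.16 on the log2 scale. Among other genes, the xyloglucan enzyme gene XTH18 was at least 37.3-fold and the glucosyltransferase gene UGT76B1 at least 15.5-fold lower, and AT3G28220 was at least 19.2-fold and AT1G76110 at least 11-fold higher.

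In this contrast 7834 probe sets were called (52.9%), 4752 higher and 3082 lower in ago1-27, with 2380 and 1625 changed at least 2-fold, and 8668 had an unadjusted p under 0.05. Without the 2 arrays that lay apart 8977 were called. Over all probe sets the median log2 change was 0.17, a shift included in every change given here. It bears on the balance of calls: 60.7% were higher as deposited, and 53% after median centring (4114 higher, 3644 lower). Of the 24 low-oxygen genes 23 fell, 0 rose and 1 was not called (AT3G10020, log2 change 0.22 ± 0.42), with the same counts adjusted over the list alone. The list's median was -4.72, or -4.63 with bounds (camera adjusted p = 1.8e-17, adjusted p = 0.26 with an estimated correlation, fry adjusted p = 5.6e-06), and the medians of 10000 random lists matched in expression ranged from -0.64 to 0.9. The random lists were drawn without regard to correlation between genes, estimated at 0.4 for the low-oxygen list. Their range can therefore be too narrow for such a list. Of 5 glycolysis and fermentation genes 4 fell, also adjusted over the list alone, among them GAPC2 by 0.75 and TPI by 0.39 on the log2 scale, while PPDK was not called. PDC2 and AT4G17260 belong to both lists (glycolysis median -0.75, camera adjusted p = 0.004, adjusted p = 0.27 with an estimated correlation, fry adjusted p = 8.9e-06). All 8 photosynthesis genes rose, also adjusted over the list alone, with a median of 1.07 (camera adjusted p = 0.001, adjusted p = 0.69 with an estimated correlation, fry adjusted p = 0.00018). The low-oxygen genes part the arrays by labelled genotype and not by labelled treatment. An exchange of labels between the WT_dark and ago1-27_submerged arrays is therefore not excluded. Every contrast between 2 groups rests on the labels as deposited. Under the exchange the submergence contrasts would compare genotypes, and the genotype contrasts would compare treatments. The interaction would keep its value, since both exchanged groups enter it with the same sign. The GAPDH 3' to 5' ratio moved with the same label as these lists, at 1.93 ± 0.27 in ago1-27 and 1.42 ± 0.111 in wild type (SD, n = 3 each).

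Of 9 microRNA targets 2 rose and 2 fell in this contrast, the same adjusted over the list alone. PHV, a leaf polarity gene, was higher by 0.96 ± 0.22 and SNZ was higher, with both groups under the low-signal limit and no call with a floor on low signals (adjusted p = 0.39). APS3, an ATP sulfurylase gene, and AT3G15640 were lower by a log2 change of -1.33 ± 0.4 and -0.63 ± 0.2. The list's median was 0.02 with a test direction of down (camera adjusted p = 0.89). CCS and AGL16 were not called (0.26 ± 0.29 and 0.02 ± 0.16). Of 5 starvation genes AKINBETA1, MCCA and ATG8E rose (0.98 ± 0.21, 0.79 ± 0.31 and 0.61 ± 0.22) and IVD fell (-0.81 ± 0.18), and 4 rose and 1 fell adjusted over the list alone (median 0.67, camera adjusted p = 0.74). Of 4 silencing genes TGH rose and SQN fell, as adjusted over the list alone (0.01, test direction down, 0.96). In the list of heat and oxidative stress 2 of 4 fell, the zinc finger gene STZ by 2.5 on the log2 scale and AT1G53540 at least 1.46-fold, as adjusted over the list alone (-1.62, or -0.64 with bounds, 0.21; fry adjusted p = 0.011). EXPA8 rose among 3 cell wall genes, as adjusted over the list alone (0.7, 0.57; fry adjusted p = 0.04). TOPII rose among 3 cell division genes, 3 adjusted over the list alone (1.25, or 0.83 with bounds, 0.48), and AT3G53890 rose among 6 ribosome genes, 0 adjusted over the list alone (0.02, test direction down, 0.96). Single genes lost their call without an array, here with the highest adjusted p. In the dark these were APS3 (0.073) without WT_dark 2, WT_dark 3 or ago1-27_dark 3, AT3G15640 (0.066) without ago1-27_dark 2, TGH (0.066) without WT_dark 2 or ago1-27_dark 3, and AT1G53540 (0.057) without WT_dark 1, WT_dark 2 or ago1-27_dark 3. AT3G53890 (0.14) did so without WT_dark 2, WT_dark 3, ago1-27_dark 1 or ago1-27_dark 2, ATG8E (0.098) without any array of these 6 but WT_dark 2, and SQN (0.13) and MCCA (0.23) without 7 and 9 of the 12 arrays.

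Under submergence, the comparison of ago1-27 with wild type asks what the mutation changes in submerged leaves. Again 23 of 24 low-oxygen genes were lower in the arrays labelled ago1-27, CML38 at least 48.3-fold (4820 ± 311 in wild type, 27.6 ± 7.82 in ago1-27; SD, n = 3 each; adjusted p = 3.4e-10), AT5G10040 at least 111-fold, AT5G66985 at least 83.1-fold and AT4G24110 at least 37.6-fold. PDC2 was lower by a log2 change of -4.25 ± 0.29 (SE), and AT3G10040 (HRA1) fell from 4250 ± 391 to 113 ± 108. LHCB4.2 was higher by 1.57 ± 0.22 and PSAN by 1.35 ± 0.16 on the log2 scale. Among other genes, XTH18 was at least 44.8-fold and the glutathione transferase gene GSTU25 at least 5.15-fold lower, and BCAT4, an aminotransferase of glucosinolate synthesis, rose from 94.2 ± 31.1 to 1480 ± 314 (log2 change 4.02 ± 0.28, adjusted p = 8.2e-07).

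In this contrast 6591 probe sets were called (44.5%), 3956 higher and 2635 lower in ago1-27, with 1666 and 1372 changed at least 2-fold. An unadjusted p under 0.05 was found for 7759, the median over all probe sets was 0.17, and 7134 were called without the 2 arrays that lay apart. As deposited 60% of the calls were higher, and after median centring 53.2% (3433 higher, 3016 lower). Of the 24 low-oxygen genes 23 fell, 0 rose and AT3G10020 was not called (0.18 ± 0.42), with the same counts adjusted over the list alone. Their median was -4.82 (camera adjusted p = 5.5e-21, adjusted p = 0.26 with an estimated correlation, fry adjusted p = 5.6e-06), and random lists, with the same limit as in the dark, ranged from -0.66 to 0.68. Of 5 glycolysis and fermentation genes 4 fell, and 5 adjusted over the list alone (median -0.75, camera adjusted p = 0.002, adjusted p = 0.26 with an estimated correlation, fry adjusted p = 1.1e-05). All 8 photosynthesis genes rose, also adjusted over the list alone (0.89, camera adjusted p = 0.002, adjusted p = 0.69 with an estimated correlation, fry adjusted p = 0.0013). The GAPDH ratio was 1.97 ± 0.261 in ago1-27 and 1.29 ± 0.0648 in wild type, and the actin ratio 11.4 ± 0.989 and 6.3 ± 0.63. The ubiquitin ratio was 3.27 ± 0.328 in ago1-27 and 2.83 ± 0.204 in wild type, and the 25S control 8320 ± 1700 and 17400 ± 1260. Of 9 microRNA targets PHV rose by 1.14 ± 0.22 on the log2 scale, SNZ rose at least 1.79-fold and AGL16 fell by 0.62 ± 0.16, the same adjusted over the list alone (median 0.05, test direction down, camera adjusted p = 0.91). CCS was not called (0.05 ± 0.29).

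IVD fell among 5 starvation genes, as adjusted over the list alone (median 0.29, test direction down, camera adjusted p = 0.96). DDL fell among 4 silencing genes, as adjusted over the list alone (-0.13, 0.57), and AT3G53890 rose among 6 ribosome genes, as adjusted over the list alone (0.21, 0.74). In the list of heat and oxidative stress STZ fell by 3.7 on the log2 scale and AT1G53540 at least 1.06-fold, as adjusted over the list alone (-2.17, or 0.23 with bounds, 0.23; fry adjusted p = 0.014). Of 3 cell wall genes EXPB1 rose at least 1.99-fold and EXPA8 rose, as adjusted over the list alone (0.79, 0.42; fry adjusted p = 0.029). All 3 cell division genes rose, as adjusted over the list alone, AUR2 at least 2.12-fold, TOPII at least 2.79-fold and AUR1 by 1.85 on the log2 scale (1.93, or 1.48 with bounds, camera adjusted p = 0.23; fry adjusted p = 0.021). Replicate 3 of submerged ago1-27 stood apart here, with a list median log2 signal of 9.17 against 7.32 and 6.96 on replicates 1 and 2 and at most 6.08 in submerged wild type. Without it the log2 change of TOPII was 1.08 in place of 1.93, less than the bound given. Single genes lost their call without an array, here with the highest adjusted p. Under submergence these were TPI (0.094) and EXPA8 (0.11) without WT_submerged 2, WT_submerged 3, ago1-27_submerged 1 or ago1-27_submerged 2, PRK (0.087) without WT_submerged 3, ago1-27_submerged 1 or ago1-27_submerged 2, and TOPII (0.076) without WT_submerged 1, WT_submerged 2 or ago1-27_submerged 3. RCA (0.14) did so without WT_submerged 2, WT_submerged 3, ago1-27_submerged 1 or ago1-27_dark 3, AT1G53540 (0.11) without any of these 6 arrays but ago1-27_submerged 3, and AT3G53890 (0.05) without WT_submerged 2. Without WT_submerged replicate 3 CCS was called lower in ago1-27, at -0.41 (0.044).

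**Figure D3:**
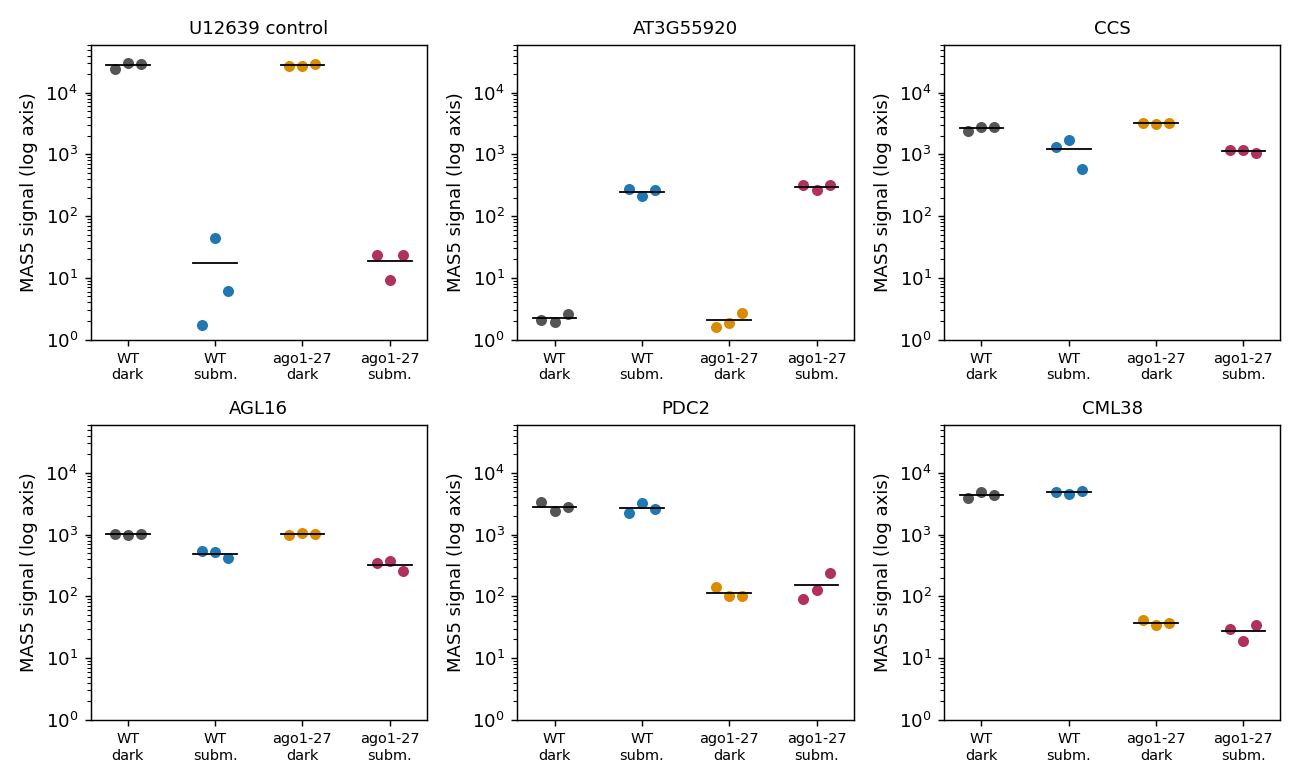
Signal of the U12639 control probe set, AT3G55920, CCS, AGL16, PDC2 and CML38 (vertical axis, log scale) on each array, by labelled group; points are arrays and lines are group means (n = 3). PDC2 and CML38 part by labelled genotype, the others by labelled treatment.

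The genotype effects in the dark and under submergence were close to each other across probe sets. CML38, PDC2, AT5G10040 and XTH18 were lower, and LHCB4.2 and PHV higher, in ago1-27 at both treatments. Of the probe sets called higher 3157 were shared (1270 expected for independent lists), and of those called lower 2128 (548 expected), while 18 were called in opposite directions. The log2 changes correlated across probe sets with a Pearson r of 0.89 and a Spearman rho of 0.85, and genes are not independent replicates. In total the genotype contrasts shared 5285 calls, or 5964 without the 2 arrays that lay apart, and the submergence contrasts 289.

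Lists with fewer than 3 measured genes were not tested as groups. PDF1.2, a defensin gene of the jasmonate list, was higher in ago1-27 by a log2 change of 2.15 ± 0.37 in the dark and 1.69 ± 0.37 under submergence, and SAG101, of the salicylic acid list, was lower, at -1.33 ± 0.22 and -0.66 ± 0.22 (highest adjusted p = 0.098 under submergence, where the call ended without WT_submerged 1 or 3 or any ago1-27_submerged array). COR27 and AT4G33980 (COR28), of the clock list, were lower in ago1-27. COR27 was lower by a log2 change of -1.33 ± 0.24 in the dark and at least 4.55-fold under submergence, and AT4G33980 at least 9.46-fold and 5.04-fold. COR27 also fell under submergence in ago1-27, at least 2.43-fold. The cold-response gene COR47 of the abscisic acid list was higher in ago1-27 by 1.85 ± 0.22 and 1 ± 0.22, and COR15A was lower, at -1.89 ± 0.24 and -0.89 ± 0.24. The ethylene genes EIN3 and RTE1 were not called in any contrast (submergence in wild type, 0.07 ± 0.11 and 0.08 ± 0.16). DFR, of the flavonoid list, was higher in ago1-27 by 1.53 ± 0.56 in the dark (highest adjusted p = 0.12, the call ending without WT_dark 2, WT_dark 3, ago1-27_dark 1 or ago1-27_dark 3) and at least 2.8-fold under submergence, and AT4G14090 at least 1.19-fold under submergence (0.12, ending without WT_submerged 1, WT_submerged 2, ago1-27_submerged 2 or ago1-27_submerged 3). FMA, the only guard cell marker measured, was at least 1.43-fold higher in ago1-27 in the dark (0.13, ending without WT_dark 2, WT_dark 3, ago1-27_dark 1 or ago1-27_dark 2). No root marker passed the filter on low signals and no flower marker is named by the annotation. The counts of these lists adjusted over the list alone are not given, since they hold at most 2 genes.

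The interaction asks whether the submergence effect differs between the genotypes. FHL, a gene of phytochrome A signalling, fell from 1030 ± 114 to 263 ± 28.6 with submergence in wild type and lay at 84.6 ± 19.9 and 89.8 ± 9.59 in ago1-27 (SD, n = 3 each; interaction 2.08 ± 0.27 on the log2 scale, SE; adjusted p = 0.015). The FHL signals in ago1-27 lay near the low-signal limits of those arrays, 85.2 to 92.3 in the dark and 89.1 to 120 under submergence. A fall from there would be poorly measured, so the size of the FHL interaction is uncertain. AT3G22240 lay at 18500 ± 656 and 15100 ± 2250 in wild type and rose from 2350 ± 663 to 11800 ± 4390 in ago1-27 (2.6 ± 0.36, adjusted p = 0.015). AT4G12500 rose from 216 ± 43.1 to 1990 ± 1080 in wild type and was at 98.2 ± 45.4 in submerged ago1-27 (-3.86 ± 0.56, adjusted p = 0.016), and AT4G12490, of the same family, gave -3.03 ± 0.56. AT2G05540 gave -2.15 ± 0.25, from 129 ± 27.1 and 339 ± 58 in wild type and 865 ± 64.3 and 516 ± 43 in ago1-27 (adjusted p = 0.013).

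In all, 42 of 14812 probe sets were called for the interaction, 21 more positive and 21 more negative in ago1-27, 41 of them by at least 2-fold, and 2187 had an unadjusted p under 0.05. In 3 of the 42, among them AT3G09480 and AT2G20560, both groups of a genotype lay under the low-signal limit, so that the size of the interaction is not measured. The actin 3' to 5' ratio moved in opposite directions with submergence in the genotypes, like an interaction. No list was called. The low-oxygen list had a median of -0.04 (camera adjusted p = 0.74; 1 fell adjusted over the list alone), glycolysis and fermentation 0.09 (0.74), starvation -0.32 (0.42; 1 fell adjusted over the list alone), and photosynthesis -0.31 (0.076; 3 fell adjusted over the list alone). The medians of the others were: ribosome 0.16 (0.4), microRNA targets 0.05 (0.89), silencing -0.23 (0.59; 1 fell adjusted over the list alone), heat and oxidative stress -0.03 (0.99, test direction up), cell wall -0.02 (0.99, test direction up) and cell division 0.86 (0.42). The fry adjusted p of these lists ranged from 0.34 to 0.99. Of the 22 genes named by the rule, 19 were not called without some array, and AT2G05540, AT3G50560 and AT3G27770 were called without each of the 12 in turn. Without WT_submerged replicate 1 the adjusted p was 0.052 for FHL and for AT3G22240. The highest was 0.059 for AT4G12500, lost without WT_submerged 1, ago1-27_dark 2 or ago1-27_dark 3, and 0.14 for AT4G12490, lost without 9 of the 12. The count was 5 without WT_submerged replicate 1, 7 without ago1-27_dark replicate 3, 12 without ago1-27_dark replicate 2, and 17 without ago1-27_dark replicate 1. It was 18 without WT_submerged replicate 2, 19 without WT_dark replicate 3, 21 without ago1-27_submerged replicate 2, 23 without WT_dark replicate 2, 69 without ago1-27_submerged replicate 1 and 727 without WT_dark replicate 1. It was 26 without a variance trend, 78 with a stricter filter, 83 with a floor on low signals, 1798 with array weights and 1203 without the 2 arrays that lay apart. The low-oxygen list had a median interaction of -0.74 (adjusted p = 0.0036) without ago1-27_submerged replicate 3.

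**Figure D4:**
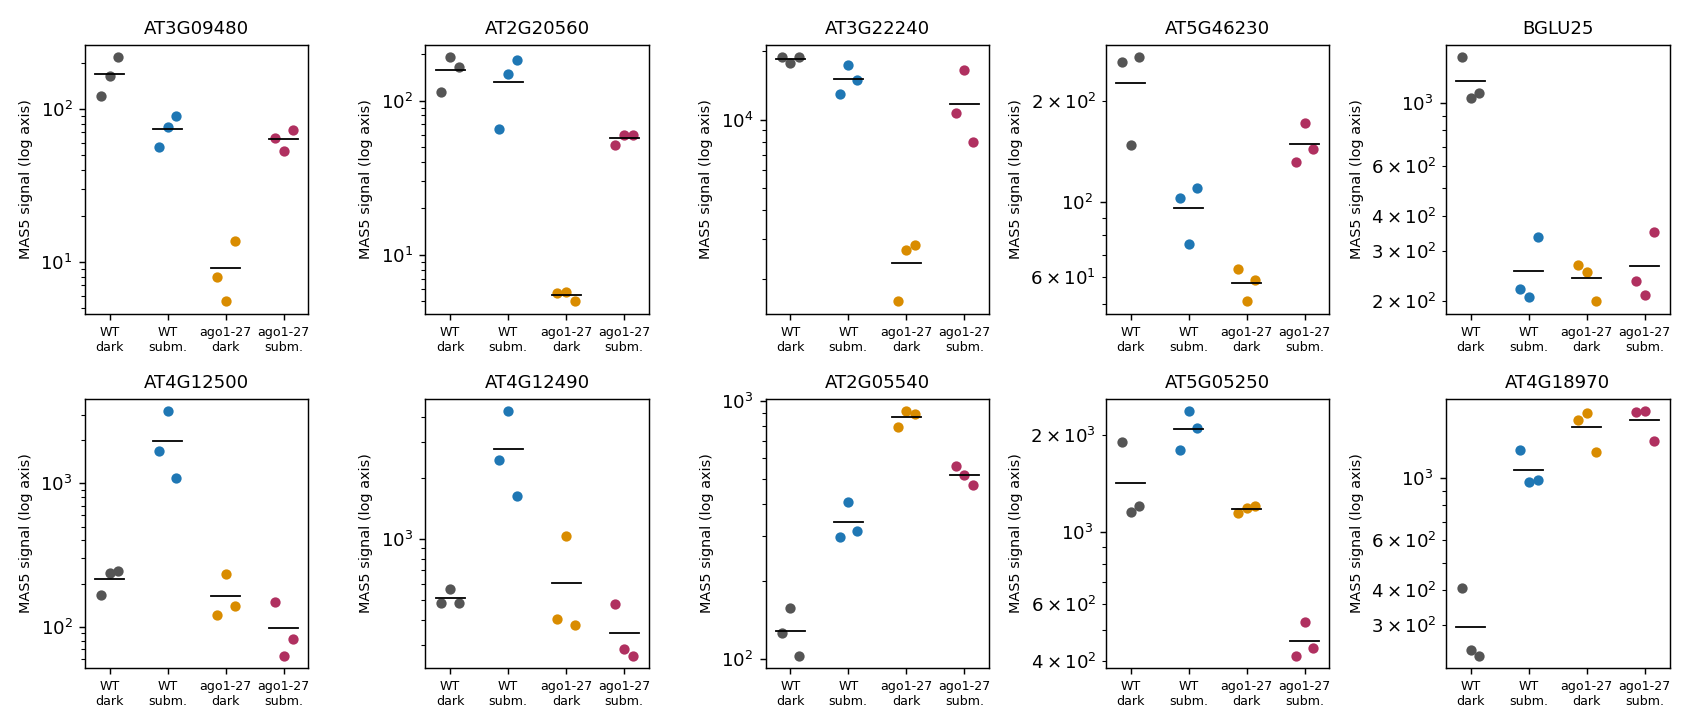
Signal (vertical axis, log scale) of 10 genes, those with the 5 most positive and the 5 most negative fitted interactions, on each array by labelled group; points are arrays and lines are group means (n = 3). AT3G09480 and AT2G20560 lie under the low-signal limit in both ago1-27 groups and AT5G46230 in ago1-27 in the dark, so the size and rank of their interactions are not measured. AT4G12500 is high in submerged wild type alone, with a mean of 1990.

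The size of the submergence response was compared between the genotypes over probe sets called for the mean effect of both and changed at least 2-fold. Of 367 such probe sets 209 rose and 158 fell, and 210 changed less in ago1-27 than in wild type. The median change in the direction of the mean effect was 1.44 in wild type and 1.27 in ago1-27. The median signed interaction was -0.12, with quartiles of -0.69 and 0.47, and 53 of 100 regroupings of the residuals, the real data included, gave a median as far from 0. It was 0.05 without ago1-27_submerged replicate 1. With all arrays limma's fry did not call the difference, but it called ago1-27 the weaker without WT_dark replicate 1 (-0.45) and without the 2 arrays that lay apart (-0.54).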

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

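The tests of exchanged labels, of a blocked induction, of low oxygen in the dark wild type and of genetic makeup were chosen after the result was seen; the test of the other control probe sets and the counts over other splits of the arrays and regroupings of the residuals were chosen before.

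Of the 24 low-oxygen genes 23 were lower in ago1-27 in both labelled treatments, and the list's median log2 signal was at least 11.72 on each array labelled wild type and at most 8.36 on each labelled ago1-27. On the labels as deposited, a block by ago1-27 of the induction by submergence is argued against by wild type, where the list's median change was 0.14, under the change of 1 that induction would need. A candidate explanation is an exchange of the labels of the WT_dark and ago1-27_submerged arrays: these 6 arrays, and 0 of the other 6, lay on the side of the list's midpoint (9.27) opposite to their labelled treatment, but this restates the pattern and does not count for the exchange. Plants of the WT_dark group may themselves have been low in oxygen, with ago1-27 holding these genes low in both treatments. That would give a median interaction near 0. The interaction has the same value with or without an exchange, so this list cannot tell the explanations apart. Its median interaction was -0.04, and -0.74 (camera adjusted p = 0.0036) without ago1-27_submerged replicate 3. An effect of the genotype that the labels name stays open and untested, AT3G10020 did not follow the list, and no comparison was made with other groups than the labelled ones.

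The control probe set U12639 belongs to no comparison of the report, and its signal was 27800 ± 2000 on the 6 arrays labelled dark and 18.1 ± 15.9 on the 6 labelled submerged. With AT3G55920 (2.14 and 273) it made 2 of 22810 probe sets that part the labelled treatments by at least 4 on the log2 scale, against 29 for the labelled genotypes and 0 for the crossed split. Different handling of the hybridisation and labelling controls is argued against, since the widest gap among the 63 other control probe sets was -0.05, so that none parted the treatments. A difference in genetic makeup between the plants behind the arrays labelled dark and submerged may underlie such probe sets, but the 2 found are the observation that raised the question and do not count for it, and a response to treatment cannot be told apart from it. If the labels were exchanged as above, the 6 arrays with the U12639 signal would be those of a single genotype. That was not tested apart from the list. Of the microRNA targets, CCS and AGL16 also fell with labelled submergence in both genotypes. PHV instead followed the labelled genotype in both treatments, and SNZ was called in every contrast between 2 groups. As a list the microRNA targets were not called in any contrast, so they do not decide the question.

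For 42 probe sets the test of the interaction gave a submergence effect that differed between wild type and ago1-27. The fit gave 4.06 for AT3G09480 and 3.72 for AT2G20560, both under the low-signal limit in both ago1-27 groups, and 2.56 for AT5G46230, under it in ago1-27 in the dark, so that these sizes and their rank are not measured. Among the others named, it was more positive in ago1-27 for AT3G22240 (2.6) and BGLU25 (2.36), and more negative for AT4G12500 (-3.86), AT4G12490 (-3.03), AT2G05540 (-2.15), AT5G05250 (-1.94) and AT4G18970 (-1.82), on the log2 scale. Of 100 regroupings of the residuals of a fit without interaction, 3 gave as many calls, the real data included, a share under 0.05. The highest other called 215, several times the real count, as a structure of the samples can give, which was not tested as its cause. The regroupings take all arrays to vary alike. The SD of log2 differences between replicates was 0.39 for ago1-27_dark 1 and 3 but 0.725 for WT_dark 1 and 2, so the share does not settle whether chance is excluded. WT_dark replicate 1 stood apart from its group, and 727 probe sets were called without it, against 5 without WT_submerged replicate 1; a structure of the arrays and a genotype effect were not separated, and the other arrays that move the count are given with it in the report.

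Other splits of the arrays, or regroupings of the residuals, were also counted for the remaining results. For submergence in wild type (1048 calls, highest other split 70), in ago1-27 (1241 and 0) and for genotype in the dark (7834 and 0) and under submergence (6591 and 0), 1 of 10 splits gave as many, the real split, and 10 are too few for a share under 0.05. For the 9 list tests called, of 50, at most 3 of 10 splits gave a p as small, the real split included, and 10 are again too few; another split did so for the cell wall list in ago1-27, glycolysis and fermentation between genotypes in the dark and photosynthesis between genotypes under submergence. For the calls shared by the submergence contrasts (289, highest other 1) and by the genotype contrasts (5285, highest other 0), 1 of 100 pairs of splits, the real pair, shared as many, but no other pair called enough probe sets to do so, and this count decides nothing beyond the 10 splits of each contrast. For the size of the response, 53 of 100 regroupings of the residuals gave a median interaction as far from 0 (0.12, highest other 0.61), so that chance is not excluded. No test of outlying arrays was made, though array weights were fitted as an alternative.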

How the results depend on the processing

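The exclusion of 2 arrays was chosen after the result was seen; all other alternatives were chosen before.

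Calls for genotype (7834 in the dark, 6591 under submergence) and those shared by the genotype contrasts (5285) stayed within 1.5 times under every alternative, from 6533 to 8281, from 5214 to 7172 and from 4385 to 5779 with each array left out in turn. With each array left out, a group of 2 arrays was assumed to vary like the other groups. Calls for submergence ranged from 320 (without WT_submerged replicate 1) to 2506 (without WT_dark replicate 1) in wild type, and from 352 (without ago1-27_dark replicate 2) to 1865 (without WT_dark replicate 1) in ago1-27. The calls they shared ranged from 118 to 546, the interaction from 5 to 727, the list tests called, of at most 50, from 7 to 10, and the median of the response size from -0.45 to 0.05.

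With array weights, 4419 (wild type), 2701 (ago1-27), 1798 (interaction) and 1025 (shared) were called. Without WT_dark replicate 1 and ago1-27_submerged replicate 3 together the numbers were 3866 in wild type, 1203 for the interaction and 606 shared, and the response size was -0.54, called by fry. With only the 6 arrays compared 431 were called in wild type and 160 shared, where fewer arrays estimate the variance. This setting gives no value for the interaction or the response size, and the list tests called were not counted in it. The interaction gave 78 with the stricter filter, 83 with a floor at the 25th percentile and 26 without a trend. With an estimated correlation 0 of 50 list tests were called with camera, against 9 with the preset correlation, from 4 lists, and 13 with fry. Apart from these constructions the cause was not tested.

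The low-oxygen list in ago1-27, not called at 0.18, reversed to -0.31 without ago1-27_submerged replicate 3 (adjusted p = 0.0084) and also to -0.31 without the 2 arrays (0.014), over a range up to 0.42 with each array left out. CCS between the genotypes under submergence, not called at 0.05, reversed to -0.41 without WT_submerged replicate 3, over a range up to 0.37. The cause was not tested. Of 5480 values of called named genes under the alternatives, 5079 kept direction and call, 401 lost the call and 0 reversed; of 233 values of called list tests 216 kept both and 17 lost the call.

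With the replicate number as a block, which the pairing check does not bear out, calls were 1101, 1179, 7793 and 6589 in the order of the contrasts, 50 for the interaction, 280 and 5304 shared, 10 list tests, and -0.13 for the response size. Signal over background limits folds: where a group lay under the 40th percentile, only a bound is given.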

Other observations

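The tests of 36 gene families in the 5 contrasts (180 tests) were chosen after the result was seen, and with an estimated correlation none was called (adjusted p = 0.92 for each family called here).

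Signals of genes encoded by the plastid genome were lower under submergence relative to other genes by camera, though not by fry. How well the 3' labelling captures transcripts of plastid-encoded genes was not examined, so these are changes of signal. Of 66 such genes 63 had a negative change in wild type, with a median of -0.25 and 0 called (camera adjusted p = 1.4e-07, fry p adjusted over all families 0.31), and -0.33 after median centring. In ago1-27 the median was -0.38, with rps2, petN and accD called lower (-1.03, -0.65 and -0.9 ± 0.21, SE, n = 3 per group; camera adjusted p = 6.3e-11, fry 0.14), and 0 called adjusted over the list alone. With each array left out the medians ranged from -0.3 to -0.17 and from -0.59 to -0.19. RNA signs moved in the same comparisons and were not separated from these changes. The 25S ribosomal RNA control went from 20000 ± 1520 to 17400 ± 1260 in wild type and from 15600 ± 840 to 8320 ± 1700 in ago1-27 (SD, n = 3 each). The actin 3' to 5' ratio went from 7.95 to 6.3 and from 8.02 to 11.4, and the ubiquitin ratio from 2.69 to 2.83 and from 2.72 to 3.27.

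In wild type the XTH and TUB families were called by camera, while the EXPA (adjusted p = 0.44) and TBL (0.83) families of cell wall genes were not. Of 5 XTH genes 3 rose, XTH33 (2.04), XTH16 (1.67) and XTH19 (1.42), with a median of 1.42 (camera adjusted p = 0.012, but 0.12 without WT_dark replicate 1 and 0.15 without the 2 arrays that lay apart, and a median of 0.42 with an adjusted p = 0.34 with no filter). Of 5 beta-tubulin genes TUB1 rose from 202 to 581 (1.52 ± 0.28), and TUB6 (0.61) and TUB5 (0.5) rose, with a median of 0.59 (0.015, but 0.083 without WT_dark replicate 1 and 0.11 without the 2 arrays). The 7 RPL genes all belong to the 66 plastid-encoded genes, so their result in wild type repeats part of that one, with a median of -0.36 (0.048, up to 0.19 with an array left out, 7 of 12 ending the call, and 0.12 without the 2 arrays). In submerged plants 5 CML genes had a median of -1 in ago1-27 against wild type, with 2 called lower, CML37 and CML38 (0.037, but 0.14 without ago1-27_submerged replicate 3 and 0.11 without the 2 arrays). CML38 is also a gene of the low-oxygen list, so this result repeats part of that list, and no test was made without it. In the dark the family was not called (0.25), with a median of -1.46, 3 genes lower and CML41 higher. The directions of the called families were kept under quantile normalization and median centring, where RPL was not called in either (0.088 and 0.079) nor CML after centring (0.053). RPL was also not called by fry (0.2), with no filter (0.058), a stricter filter (0.071), a floor on low signals (0.054) or a pseudocount (0.053). CML was also not called with the stricter filter (0.086), and its median was -0.47 with no filter.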
